A study of Mus musculus with 221 samples.

How the data were processed

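Gene expression was measured in 221 single cells from microdissected medial neocortex of C57BL/6J mouse embryos at E18.5. The cells came from 2 independent pools of 8 neocortices each, dissociated to a suspension. Pool 1 gave 122 cells and pool 2 gave 99. Per the submitters' notes, cells were captured in a microfluidic chip (Fluidigm C1), cDNA was made with a full-length template-switching kit (SMARTer v4 Ultra Low) and libraries with a transposase kit (Nextera XT). Cell names also carry a well position and a letter A or B, called the suffix here. Pool 1 had 57 cells with suffix A and 65 with suffix B, and pool 2 had 66 and 33. The labels do not say whether the suffix marks a chip or a run.

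The deposited values are TPM, transcript shares scaled to a fixed total per cell, made by the authors with TopHat2 2.0.14, Bowtie2 2.2.6 and Cufflinks 2.2.1 on the mouse assembly mm10. The values of every cell add up to 1000000 over 23244 features. No value is 0. In each cell the lowest value, called the floor, is shared by all features without signal and lies between 1.33 and 3.00 TPM (median 1.83). Divided by its cell's floor, a value has at most 6 significant digits in 99.5% of cases, the pattern left when FPKM values below 1 are set to 1 before the scaling to TPM. A gene was therefore taken as detected when its value exceeded the floor of its cell, because the limit of 1 TPM chosen before the data were examined is met by every value. In all cells 8945 features lie at the floor, among them all 92 spike-in controls. The number of genes above the floor was 2146 to 6727 per cell, with a median of 4071.5 in pool 1 and 3954 in pool 2. Read numbers are not in the deposited tables, so the depth per cell is unknown and no interval that needs it is given. Both deposited tables hold identical values. The highest correlation between any 2 cells was 0.644 (Pearson r on log2 values), so no cell was entered more than once.

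Values were taken as log2(TPM + 1). Cells were grouped by Ward linkage on the first 10 principal components of 80 standardized marker genes. Of 101 marker symbols fixed before the data were examined, 98 were in the table and these 80 were above the floor in at least 1 cell. The tree was divided into 10 clusters. A cluster took the name of the class with the highest marker score when at least 3 of its markers were above the floor in 50% of the cells, and when its 10 leading genes held at least as many of its own markers as of another class. Names of blood, vessel and meningeal cells were not given to clusters with neuronal levels of Neurod6, and single cells were left unnamed. Clusters with the same name were joined. This naming rule was set after the clusters had been seen. Classes are written with "-like" because they rest on transcripts alone. Shares of cells have exact (Clopper-Pearson) 95% intervals, which cover counting error only.

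Cells of 1 pool are not independent animals, so the pool was the replicate (n = 2 per class). Genes were compared with limma 3.58.1 in R 4.3.3 (lmFit, then eBayes with an intensity trend and robust variances) on the mean log2(TPM + 1) per class and pool, two-sided, with Benjamini-Hochberg adjustment. A gene was called at an adjusted p below 0.05 and a log2 difference of at least 1 in size. Genes above the floor in at least 10 cells were kept (10746), and 10696 were tested after markers and spike-ins were left out. Classes needed at least 5 cells in each pool, which gave 8 profiles and 4 residual degrees of freedom. The intermediate progenitor-like class has 4 cells in pool 1, so its comparisons used a minimum of 4 cells (10 profiles, 5 degrees of freedom). That minimum, and the comparisons with an unnamed group called cluster 9, were chosen after the cell numbers were seen. All classes share the spread estimate. Errors are standard errors (SE) of this fit.

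Classes within a pool come from the same animals, so the pool number pairs them by design. The deviations of pool 2 from the class means were correlated by at most 0.0379 across genes between any 2 of the radial glia-like, excitatory neuron-like and interneuron-like classes and cluster 9, and pool was left out of the model. The intermediate progenitor-like class was not in this check. With the pool as a block, the calls numbered 777 for radial glia-like against excitatory neuron-like cells, 77 for radial glia-like against intermediate progenitor-like cells, 108 for intermediate progenitor-like against excitatory neuron-like cells and 48 for interneuron-like against excitatory neuron-like cells.

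Fixed before the data were examined were 20 gene lists with 241 symbols, kept apart from the markers. Of these, 18 were tested with camera (limma) at a preset correlation of 0.01 and again with an estimated correlation, adjusted over the 18 lists of each of 6 comparisons. The fry test (limma), which does not set a list against the other genes, was run beside camera. The Y-linked and X inactivation lists served as a check. The symbols Gapdh, Btg2, Aqp4 and Hbb-bt were not found. Genes are named by a rule fixed before the data were examined: Hopx, Eomes, Pax6 and Sox2; up to 12 genes per direction with the largest called difference of 1 sign in both pools, without predicted genes; up to 4 members per list with the largest difference. Correlations of genes with Hopx over radial glia-like cells (Spearman) were computed within each pool, for 5167 genes, with no p-value. The median over each of 17 lists with at least 3 members measured was set against 10000 random lists of like expression. Gene coordinates are from GENCODE for GRCm38, the same assembly as mm10.

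The limma comparison of radial glia-like with excitatory neuron-like cells was tested on simulated data. Groups of the measured radial glia-like sizes, among others, were drawn from the excitatory neuron-like cells. The cells left over formed the excitatory neuron-like group, which was therefore smaller than the measured one. The values above the floor of randomly drawn genes were multiplied. Comparisons with intermediate progenitor-like cells were not simulated. Cells at the floor stayed there, so genes planted at 16-fold had a median log2 difference of only 1.30. Limma called 3 of 68 genes planted at 4-fold, 5 of 66 at 8-fold and 10 of 66 at 16-fold, and 0 of 10496 unchanged genes. A missing call is therefore weak evidence of no difference. In the simulated co-expression data, each planted gene was the permuted log2 level of Hopx plus noise small against its range. Their recovery was therefore nearly fixed, and it does not show how many weaker correlations would be found. Of these planted genes, 98 of 100 reached a correlation of 0.5 in both pools. So did 48 unplanted genes, and 38 others reached -0.5.

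Alternatives set before the data were examined were the pseudocount (0.1 or 5), no filter on low values, the pool as a block, the log2 of the mean value, weights by cell number, pool and suffix as 4 units, quantile-normalized profiles, clusters from the 1000 most variable genes, 8 or 12 clusters, leaving out cells with both Xist and Y-linked transcripts, and leaving out each pool. Added after seeing the data were the FPKM scale, radial glia-like cells with Neurod6 below 100 TPM only, leaving out pool 2 suffix B, leaving out pool 1 suffix A as well, a partial correlation given Neurod6, and 3 other references for the co-expression, among them 1000 permutations of the order of Hopx within pools. A rescaling to equal totals changes nothing because the totals are equal already, and a minimum of 2000 genes per cell removes 0 cells, so neither was run. Leaving out pool 1 suffix A was run only for comparisons without radial glia-like or intermediate progenitor-like cells. Without that suffix, pool 1 keeps only 1 radial glia-like cell. No doublet caller was run. Python 3.11.15 with numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 was used for the rest.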

Results

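The data are 221 single-cell transcriptomes of the medial neocortex of mouse embryos at E18.5, shortly before birth, when the making of neurons is ending and that of glia begins. The study's title concerns basal radial glia of the mouse neocortex that depend on Hopx, a small homeodomain protein without DNA binding of its own, and that resemble human basal radial glia. Radial glia are the neural stem cells of the developing cortex, and basal (outer) radial glia are those that have left the ventricular surface. Pool 1 held 122 cells with a median of 4071.5 genes above the floor, and pool 2 held 99 cells with a median of 3954. No group was treated, so the comparisons are between cell classes found in the same pools, with n = 2 pools per class. Every log2 difference below is given with its SE from limma, and every p is adjusted over the genes or lists tested.

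Most cells were neurons. The excitatory neuron-like class held 119 cells, 53.8% of the total (exact 95% interval 47.0 to 60.6%), with 53.3% in pool 1 and 54.5% in pool 2. Interneuron-like cells made up 12.2% (8.21 to 17.3%; 27 cells). Radial glia-like cells made up 7.69% (4.54 to 12.03%; 17 cells, 8 in pool 1 and 9 in pool 2). By suffix, 7 had A and 1 had B in pool 1, and 7 had A and 2 had B in pool 2. For excitatory neuron-like cells these numbers were 27 and 38 in pool 1, and 37 and 17 in pool 2. Class and suffix are therefore partly confounded. Intermediate progenitors, the dividing cells between radial glia and neurons, had a class of 9 cells (4 in pool 1 and 5 in pool 2) or 4.07% (1.88 to 7.59%). It joined 2 unlike clusters. The cluster of 7 cells was named on a tie, with 3 of its own markers and 3 radial glia markers (Hes5, Vim and Mfge8) among its 10 leading genes. In the cluster of 2 cells, Sox2 and Mki67 were above the floor in 0 cells. Cluster 9, with 32 cells or 14.5% (10.1 to 19.8%), took no name, although its closest class by markers was the intermediate progenitor. Its leading genes included Pcp4, Sstr2 and Neurod1. Eomes was above the floor in 17 of its 32 cells, Pax6 in 23 and Sox2 in 10. The share of 4.07% therefore leaves out cells with Eomes. As class markers, and so not as findings, Eomes was above the floor in 9 of 9 intermediate progenitor-like, 2 of 17 radial glia-like and 3 of 119 excitatory neuron-like cells. Pax6 was above the floor in 13 of 17 radial glia-like, 9 of 9 intermediate progenitor-like and 17 of 119 excitatory neuron-like cells. For Sox2 these were 12 of 17, 7 of 9 and 11 of 119, with 14 of 27 interneuron-like cells besides. Olig1, a marker of oligodendrocyte precursors, was above the floor in 10 of 17 radial glia-like cells (mean 379 TPM), against 7 of 66 and 6 of 53 in the 2 excitatory clusters. Whether it goes along with the glial genes below was not tested. The shares of the 4 named classes and of cluster 9 differed between the pools by less than their intervals. The other 17 cells fell into clusters 3 and 4, of 8 cells each, and a single cell. The shares depend on the clustering: from the 1000 most variable genes the radial glia-like share was 19.5% and no intermediate progenitor-like class appeared, and with 8 clusters the latter took in cluster 9 and reached 18.6%.

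Hopx, the gene in the title, had its highest mean level in radial glia-like cells. Its mean was 955 TPM over the 17 radial glia-like cells (1163 TPM in pool 1 and 769 TPM in pool 2), 279.9 TPM in intermediate progenitor-like cells, 123 TPM in cluster 9, 27.2 TPM in excitatory neuron-like and 26.3 TPM in interneuron-like cells. The intermediate progenitor-like mean rests largely on 1 cell of pool 1 with 1867 TPM (log2 level 10.87, the next in that pool 7.04). Hopx was detected in most radial glia-like cells. It was above the floor in 16 of 17 radial glia-like cells (94.1%, exact 95% interval 71.3 to 99.9%), against 7 of 9, 13 of 32, 38 of 119 and 7 of 27 in the other classes in the order above. Hopx lies on the minus strand of chromosome 5 of GRCm38 from 77086988 to 77115121. The log2 difference was 6.42 ± 0.59 between radial glia-like and excitatory neuron-like cells (adjusted p = 0.000441; 6.51 and 6.33 in the pools), 5.09 ± 0.59 against cluster 9 (adjusted p = 0.00132) and 3.65 ± 0.64 against intermediate progenitor-like cells (adjusted p = 0.0227; 4.13 and 3.17 in the pools). Between intermediate progenitor-like and excitatory neuron-like cells it was 2.77 ± 0.64 and did not pass (adjusted p = 0.0551). Interneuron-like and excitatory neuron-like cells did not differ detectably (0.02 ± 0.59, adjusted p = 0.999), and the sign of this value differs between the pools. The call against intermediate progenitor-like cells held in 10 of 14 alternatives, with log2 differences of 2.05 to 4.78 and adjusted p of 0.00228 to 0.337. The call against excitatory neuron-like cells held in 14 of 15 and was lost with clusters from the most variable genes (3.05, adjusted p = 0.0976).

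**Figure D1:**
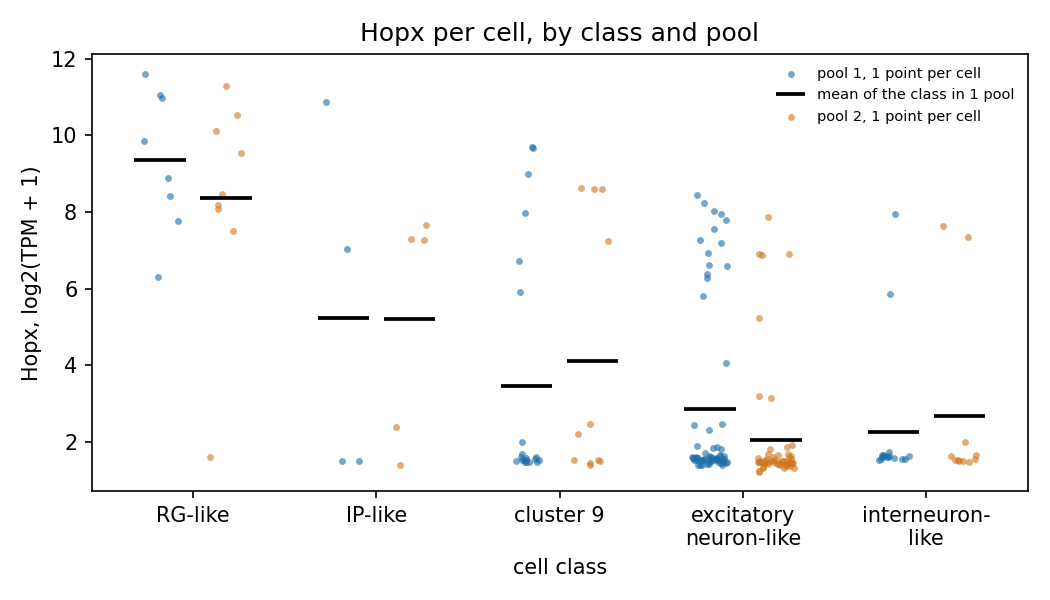
Hopx per cell as log2(TPM + 1), by cell class (horizontal axis) and pool (colour); each point is 1 cell and each black bar the mean of the class in 1 pool. In radial glia-like cells 16 of 17 points lie above the floor, against 38 of 119 in excitatory neuron-like cells.

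Radial glia-like against excitatory neuron-like cells asks which genes separate the stem cell class from the main product of the cortex. Id1 and Id3, inhibitors of basic helix-loop-helix transcription factors that respond to BMP signals, were higher by a log2 difference of 7.20 ± 0.65 (adjusted p = 0.000441) and 6.54 ± 0.71 (adjusted p = 0.000619). The metallothioneins Mt1 (6.40 ± 0.69) and Mt3 (5.93 ± 0.61) and the peroxidase Gpx8 (6.03 ± 0.58) were also higher. So were Ddah1 (5.71 ± 0.55), which breaks down asymmetric dimethylarginine, and Phgdh (5.53 ± 0.55), the first enzyme of serine synthesis. The acyl-CoA-binding protein Dbi (5.21 ± 0.35) and the lipid carrier Apoe (5.21 ± 0.69) were higher too. Dbi reached a mean of 14780.4 TPM against 615 TPM in excitatory neuron-like cells. Lower were Rab3a, a GTPase of synaptic vesicles (-4.56 ± 0.61), and Actl6b, a neuronal subunit of BAF chromatin complexes (-4.27 ± 0.51). The same held for Stmn2, a regulator of microtubules in growing axons (-4.25 ± 0.51), and Bcl11a, a transcription factor of cortical projection neurons (-3.95 ± 0.65). In GRCm38, Id1 lies on chromosome 2 (152736251 to 152737410), Id3 on chromosome 4 (136143497 to 136145755) and Rab3a on chromosome 8 (70754679 to 70758677).

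Of the 12 measured genes of the human outer radial glia list, 9 were higher in radial glia-like than in excitatory neuron-like cells (11 adjusted over the list alone), with a median log2 difference of 2.23. They included Tnc, an extracellular matrix glycoprotein (4.14 ± 0.57), Acsbg1, an acyl-CoA synthetase (4.06 ± 0.41), Pea15a (3.56 ± 0.53) and Slco1c1, a thyroid hormone transporter (3.50 ± 0.45). The camera adjusted p was 9.54e-10, and this was the only list of the comparison that also passed with an estimated correlation (adjusted p = 0.0453 with an estimated correlation). The estimate for this list was slightly negative (-0.0237). By fry the list was not alone (adjusted p = 0.00053). All other lists passed fry too, for example gliogenic factors (adjusted p = 0.000589), except deep layer and subplate, glycolysis and medial pallium patterning. Cell cycle genes were higher as well. For G2 and mitosis, 14 of 16 genes passed (16 adjusted over the list alone), among them Birc5 (4.34 ± 0.89) and Cdk1 (3.72 ± 0.52). The camera adjusted p was 1.43e-12, with adjusted p = 0.117 with an estimated correlation. For S phase, 6 of 14 passed (12 adjusted over the list alone), with Mcm3 at 4.14 ± 0.47, camera adjusted p = 1.01e-07 and adjusted p = 0.136 with an estimated correlation. For the Notch pathway, 5 of 8 genes were higher (5 adjusted over the list alone), among them the targets Hey1 (4.60 ± 0.52) and Nrarp (3.81 ± 0.48) and the receptor Notch1 (2.86 ± 0.38). This list had camera adjusted p = 3.75e-05 and adjusted p = 0.116 with an estimated correlation. Enzymes of mitochondrial fatty acid oxidation were higher in 5 of 10 cases (8 adjusted over the list alone), including Acaa2 (4.09 ± 0.49), Acadm (3.90 ± 0.57) and Acadl (3.25 ± 0.42). Here camera gave adjusted p = 4.43e-07 and adjusted p = 0.067 with an estimated correlation. For gliogenic factors 4 of 11 were higher and 1 lower (7 and 1 adjusted over the list alone). The endothelin receptor Ednrb was at 4.46 ± 0.49, Id4 at 3.32 ± 0.56 and Nfix, a transcription factor also of neurons, at -2.04 ± 0.46 (camera adjusted p = 0.000188, adjusted p = 0.067 with an estimated correlation).

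Smaller numbers passed in the remaining lists with higher values in radial glia-like cells. For extracellular matrix and integrins these were 3 of 10 (6 adjusted over the list alone), with the proteoglycan Bcan at 3.50 ± 0.43, Sparc at 3.36 ± 0.46 and camera adjusted p = 8.70e-05. For the Hedgehog pathway 2 of 7 passed (2 adjusted over the list alone), the co-receptors Gas1 (3.69 ± 0.42) and Cdon (1.62 ± 0.42), with camera adjusted p = 0.00430. For the BMP pathway and Id genes 3 of 9 passed (4 higher and 1 lower adjusted over the list alone; camera adjusted p = 0.0185). Each of these 3 lists had adjusted p = 0.116 with an estimated correlation. For the Wnt pathway 1 of 7 passed (2 adjusted over the list alone; Nkd1 1.62 ± 0.36; camera adjusted p = 0.0324, adjusted p = 0.124 with an estimated correlation). Immediate early genes of the dissociation stress list were higher in 3 of 8 cases (5 adjusted over the list alone; Fos 4.51 ± 0.97, Egr1 3.16 ± 0.72, Jun 2.31 ± 0.52; camera adjusted p = 0.0185, adjusted p = 0.136 with an estimated correlation). On the neuronal side, 9 of 14 genes of neuronal migration and cytoskeleton were lower (10 adjusted over the list alone; Tubb3 -3.56 ± 0.34, the semaphorin receptor Nrp1 -3.31 ± 0.55; camera adjusted p = 6.16e-12, adjusted p = 0.067 with an estimated correlation). So were 7 of 13 genes of synapse and excitability (7 adjusted over the list alone; Snap25 -3.01 ± 0.59; camera adjusted p = 1.53e-07, adjusted p = 0.116 with an estimated correlation) and 2 of 9 upper layer genes (4 adjusted over the list alone; Plxna4 -2.18 ± 0.48, Pou3f1 -1.84 ± 0.47; camera adjusted p = 0.00164, adjusted p = 0.0941 with an estimated correlation). Apical polarity and junctions, deep layer and subplate, medial pallium patterning and glycolysis did not pass camera, although 3 of 13 polarity genes were higher (Ctnna1 3.63 ± 0.50, Mpp5 1.67 ± 0.37, Prom1 1.49 ± 0.39).

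Radial glia-like cells had a median of 4742 genes above the floor, against 3917 and 4140 in the 2 excitatory clusters. Means of log2 values with a floor depend on how many cells lie above it. Whether this adds to the excess of higher genes was not tested. In all, 787 of 10696 genes were called, 554 higher and 233 lower in radial glia-like cells. All 787 had the same sign in both pools, which the calling from these same pools nearly fixes, here and in the comparisons below. Neuron transcripts were not absent from radial glia-like cells: Neurod6, a marker of excitatory neurons, was at 100 TPM or more in 8 of 17, with a median of 91.1 TPM against 1663 TPM in excitatory neuron-like cells, and without those 8 cells the calls numbered 793 (481 higher, 312 lower). Both radial glia-like cells from pool 2 suffix B carried beta-globin (mean 4268 TPM). The calls numbered 426 with the log2 of the mean value (217 higher and 209 lower, so without the excess of higher genes), 370 with pool and suffix as units, 153 with 12 clusters, and 0 with clusters from the most variable genes, where limma gave 1469 genes at an unadjusted p below 0.05.

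**Figure D2:**
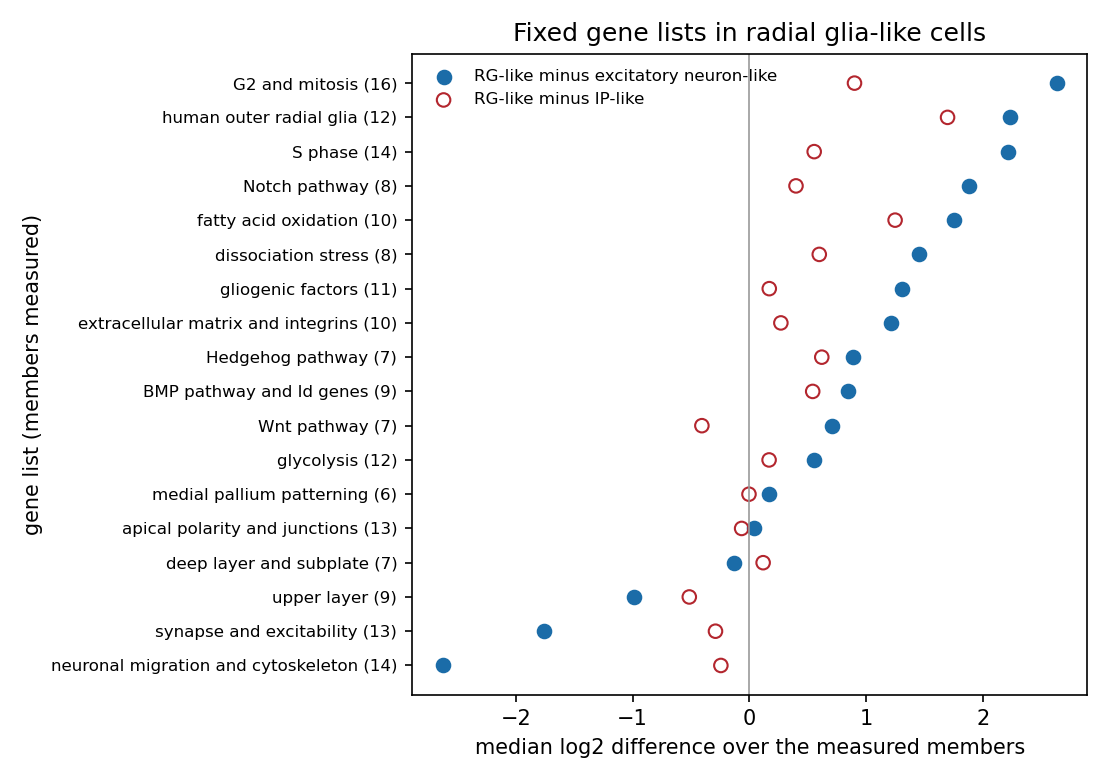
Median log2 difference over the measured members of each of 18 fixed gene lists (vertical axis, members in brackets), for radial glia-like minus excitatory neuron-like cells (filled) and minus intermediate progenitor-like cells (open). The human outer radial glia list has medians of 2.23 and 1.69, and the list of neuronal migration and cytoskeleton -2.63 and -0.24.

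Radial glia-like against intermediate progenitor-like cells asks what sets the stem cells apart from their dividing daughters. Id3 was higher by 6.59 ± 0.74 (adjusted p = 0.0069), Mt3 by 4.41 ± 0.87 and Mt1 by 4.32 ± 0.72. Psat1, an enzyme of serine synthesis (4.21 ± 0.68), and Cdo1, a cysteine dioxygenase (4.21 ± 0.72), were higher too, as were Ednrb (3.95 ± 0.52), Tnc (3.86 ± 0.61), Bcan (3.66 ± 0.44) and Tspan7 (3.64 ± 0.40). Lower were Rasgef1b, an exchange factor for small GTPases (-4.95 ± 0.61, adjusted p = 0.00828), and the neuronal RNA-binding proteins Elavl4 (-3.81 ± 0.53) and Elavl2 (-3.74 ± 0.72). Lrrn3 (-4.34 ± 0.72), the actin-binding Lima1 (-4.08 ± 0.60), and Xab2 (-4.14 ± 0.66) and Xpa (-3.59 ± 0.63), which act in nucleotide excision repair, were lower too. Tnc lies on chromosome 4 (63959785 to 64047015) and Rasgef1b on chromosome 5 (99217426 to 99729065) of GRCm38.

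Again the human outer radial glia list stood out, with 3 of 12 genes higher (8 adjusted over the list alone): Tnc, the secreted chaperone Clu (3.21 ± 0.65) and Acsbg1 (2.89 ± 0.46). Pea15a had 2.86 ± 0.67 and did not pass (adjusted p = 0.0694). The median of the list was 1.69, with camera adjusted p = 8.50e-09 and adjusted p = 0.0221 with an estimated correlation. Fatty acid oxidation had 3 of 10 genes higher (5 adjusted over the list alone): Acaa2 (3.61 ± 0.56), Acadl (2.85 ± 0.55) and Cpt1a (2.15 ± 0.36), the step that brings fatty acids into mitochondria. Its camera adjusted p was 0.000487, with adjusted p = 0.112 with an estimated correlation. The genes of G2 and mitosis were shifted upward as a list (median 0.90, camera adjusted p = 1.11e-05), but 0 of 16 passed singly, also 0 adjusted over the list alone, and adjusted p = 0.318 with an estimated correlation. Egfr (1.82 ± 0.27) was higher among gliogenic factors and Junb (1.85 ± 0.38) among the stress genes. The other 15 lists did not pass. The lists that passed numbered 2 with 12 clusters, 5 with pool and suffix as units, 6 without the cells that had both Xist and Y-linked transcripts, 12 with 8 clusters, and 7 with quantile normalization, with profiles weighted by cells or without the radial glia-like cells high in Neurod6. For apical polarity and junctions the median (-0.07) had another sign than the mean (0.17) and the test.

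Limma called 82 genes, 53 higher and 29 lower, and 1707 had an unadjusted p below 0.05. Quantile normalization changed the balance to 63 higher and 20 lower. The count was 12 with the log2 of the mean value, 50 with pool and suffix as units, 170 without the 8 radial glia-like cells with Neurod6 of 100 TPM or more (62 higher and 108 lower, so most lower), 371 with 8 clusters, and 0 with 12 clusters or with profiles weighted by cells. The main fit treats means over 4 or 5 intermediate progenitor-like cells like means over 65 or 54 excitatory neuron-like cells. The weights allow for this, so the calls named here are uncertain. With 12 clusters the radial glia-like class had 25 cells, 13 of them from the main class, while cluster 9 fell from 32 to 20 cells. The human outer radial glia list, in contrast, was higher and passed camera in all 14 alternatives. Of the 53 genes higher here, 50 were also higher against excitatory neuron-like cells, where 2.75 would be shared by independent sets; both comparisons hold the same radial glia-like cells, which raises the overlap.

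Intermediate progenitor-like against excitatory neuron-like cells follows the step from dividing progenitor to neuron. Ezr, which ties the actin cortex to the membrane, was higher by 5.30 ± 0.58 (adjusted p = 0.0023). Ccnd2, the G1 cyclin D2 (4.68 ± 0.71), the histone acetyltransferase Hat1 (4.79 ± 0.87) and Ptbp1, a repressor of neuronal splicing (4.37 ± 0.60), were higher as well. The same was found for the Notch target Nrarp (4.39 ± 0.66) and Id1 (4.30 ± 0.90). Lower were Mapt, which encodes tau (-3.44 ± 0.59), Stmn2 (-3.27 ± 0.56), Rab3a (-3.28 ± 0.62), Tubb3 (-3.24 ± 0.66), the neuropeptide gene Cck (-3.01 ± 0.56) and Dab1, the adaptor of reelin signalling (-2.85 ± 0.51). Ezr lies on chromosome 17 (6738041 to 6782784) of GRCm38.

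Neuronal migration and cytoskeleton had 4 of 14 genes lower (11 adjusted over the list alone; camera adjusted p = 1.52e-10, adjusted p = 0.0596 with an estimated correlation). Synapse and excitability had 1 of 13 lower (4 adjusted over the list alone; camera adjusted p = 4.31e-07, adjusted p = 0.2001 with an estimated correlation). Higher was G2 and mitosis with 1 of 16 (12 adjusted over the list alone; Hmgb2 3.36 ± 0.67; camera adjusted p = 2.41e-07, adjusted p = 0.262 with an estimated correlation). S phase had 2 of 14 higher (6 adjusted over the list alone; the replication genes Rfc4 3.40 ± 0.60 and Mcm5 2.90 ± 0.60; camera adjusted p = 1.04e-05, adjusted p = 0.262 with an estimated correlation), and the Notch pathway 1 of 8 (4 adjusted over the list alone; camera adjusted p = 0.00734, adjusted p = 0.2001 with an estimated correlation). Human outer radial glia genes did not pass as a list (0 of 12, 1 adjusted over the list alone, median 0.47, camera adjusted p = 0.143). In place of 5 lists, 8 passed with the log2 of the mean value and with quantile normalization. For apical polarity and junctions the test pointed the other way from the median (0.25) and mean (0.19), and for the BMP pathway the median was -0.02 and the mean 0.61. Medians of genes above the floor were 4412.5 and 5370 in the 2 intermediate progenitor-like clusters, against 3917 and 4140 in the 2 excitatory clusters. Whether this adds to the excess of higher genes was not tested. In all 126 genes were called, 102 higher and 24 lower. Of the 24 lower ones, 22 were lower in radial glia-like cells too, where 0.523 would be shared by independent sets; both comparisons subtract the same excitatory neuron-like cells, which raises the overlap. The split was 62 higher and 67 lower after quantile normalization, and 44 and 56 with the log2 of the mean value. The count was 36 with no filter on low values, 48 with profiles weighted by cells, 44 with pool and suffix as units, 206 on the FPKM scale and 0 with 8 clusters, where cluster 9 joins the class and 653 genes had an unadjusted p below 0.05 in limma.

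Interneuron-like against excitatory neuron-like cells compares the neurons that migrate in from the ventral forebrain with those born in the cortex. Nxph1, a secreted ligand of neurexins, was higher by 5.11 ± 0.68 (adjusted p = 0.00824), with the neurexin Nrxn3 (4.21 ± 0.43). Receptors followed, with the glutamate receptor subunit Gria1 (3.79 ± 0.54), Cxcr7, a receptor for the chemokine CXCL12 (3.63 ± 0.43), and the neuregulin receptor Erbb4 (3.39 ± 0.39). Lower were the adaptor Dok5 (-4.74 ± 0.59, adjusted p = 0.00558), Zfp238, a repressor that acts in cortical projection neurons (-4.23 ± 0.44), and the GABA receptor subunit Gabra2 (-4.03 ± 0.58). Further lower genes were Dab1 (-3.61 ± 0.48), Nrp1 (-3.18 ± 0.55), Id2 (-2.80 ± 0.41), Ldha (-2.73 ± 0.49) and Nfix (-2.63 ± 0.46). Nxph1 lies on chromosome 6 (8948431 to 9249032) and Dok5 on chromosome 2 (170731807 to 170879769) of GRCm38. Interneuron-like cells had fewer genes above the floor (median 3409) than the 2 excitatory clusters (3917 and 4140). Whether this adds to lower values in interneuron-like cells was not tested. Of the lists, 3 of 18 passed, all lower in interneuron-like cells. Neuronal migration and cytoskeleton had 2 of 14 genes lower (5 adjusted over the list alone; camera adjusted p = 2.11e-05, adjusted p = 0.410 with an estimated correlation). Glycolysis had 1 of 12 (2 adjusted over the list alone; camera adjusted p = 0.00809, adjusted p = 0.535 with an estimated correlation) and upper layer 0 of 9 (3 adjusted over the list alone; camera adjusted p = 0.00809, adjusted p = 0.410 with an estimated correlation). Median and test differed in sign for deep layer and subplate (median -0.21), fatty acid oxidation (-0.05) and synapse and excitability (-0.16). Limma called 51 genes, 26 higher and 25 lower; after quantile normalization the split was 41 and 22. The count was 28 with no filter on low values, 10 with the log2 of the mean value, 196 with profiles weighted by cells (65 higher, 131 lower) and 32 with clusters from the most variable genes (10 higher, 22 lower).

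Cluster 9 was compared with radial glia-like and excitatory neuron-like cells after it had been seen. Its median Neurod6 was 2294 TPM, against 1663 TPM in excitatory neuron-like cells, and it was not compared with intermediate progenitor-like cells. Radial glia-like cells exceeded it in Id1 (6.77 ± 0.65), Id3 (6.22 ± 0.71), Gpx8 (5.87 ± 0.58), Phgdh (5.29 ± 0.55) and Mlc1 (4.28 ± 0.44). They were below it in Pcp4, a calmodulin-binding protein (-4.99 ± 0.77), the somatostatin receptor Sstr2 (-4.87 ± 0.62), Cited2 (-4.29 ± 0.49) and the neurogenic factor Neurod1 (-3.68 ± 0.56). Cluster 9 had a median of 4133.5 genes above the floor, against 4742 in radial glia-like cells. The calls numbered 540, 356 higher and 184 lower in radial glia-like cells. They numbered 349 with no filter on low values, 171 with the log2 of the mean value (67 higher and 104 lower, the reverse balance), 274 with profiles weighted by cells, 352 with pool and suffix as units and 103 with 12 clusters. Of the human outer radial glia list, 7 of 12 genes were higher (10 adjusted over the list alone; median 2.02; camera adjusted p = 1.38e-09, adjusted p = 0.0469 with an estimated correlation). A further 9 lists were higher and 3 lower by camera, each lost with an estimated correlation (adjusted p = 0.106 to adjusted p = 0.340 with an estimated correlation); in place of 13 lists, 7 passed with 12 clusters. Against excitatory neuron-like cells, limma called 0 genes for cluster 9, with 578 at an unadjusted p below 0.05. By camera, G2 and mitosis (median 0.69, adjusted p = 0.000106) and gliogenic factors (0.24, adjusted p = 0.0222) were higher. Likewise by camera, synapse and excitability (-0.62, adjusted p = 9.54e-05) and neuronal migration and cytoskeleton (-0.65, adjusted p = 0.00250) were lower, with 0 members called in each list. Adjusted over the list alone, 2 migration genes were higher and 5 lower, and 0 passed in the other 3 lists. None of the 4 held (each adjusted p = 0.453 with an estimated correlation), and for deep layer and subplate the median (-0.03) and mean (0.01) differed in sign. The count of 0 genes was 35 with profiles weighted by cells and 6 with 12 clusters.

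Within radial glia-like cells, the question was which genes go along with Hopx from cell to cell. The human outer radial glia list, with 9 members measured here, did so by its median in both pools. Its median Spearman correlation with Hopx was 0.45 over the 8 cells of pool 1 and 0.40 over the 9 cells of pool 2, above 99.9% and 99.6% of random lists of like expression. Against lists drawn from genes called higher in radial glia-like than in excitatory neuron-like cells, it was above 98.66% and 95.71%. Random lists were drawn gene by gene, without regard to genes that vary together. A list of co-varying genes can therefore reach an extreme percentage more easily than these lists do. Pea15a (0.71 and 0.63), Clu (0.67 and 0.52) and Slco1c1 (0.50 and 0.48) correlated positively in both pools. Acsbg1 (0.45 and 0.22), Ptprz1 (0.24 and 0.12) and Ptn (0.07 and 0.40) were positive but weak in at least 1 pool. Sall1 showed no correlation (-0.0 and -0.017). Tnc (0.74 and -0.05) and Stat3 (-0.33 and 0.50) did not keep a sign. Of 17 lists, this was the only one above 95% of random lists in both pools; S phase (median 0.39 and 0.00), Notch pathway (0.35 and 0.08), apical polarity and junctions (0.35 and -0.11) and medial pallium patterning (0.38 and -0.28) exceeded that level in pool 1 alone. Over all 5167 genes, the correlations with Hopx in pool 1 and pool 2 were themselves correlated by 0.107, above 99.7% of 1000 genes of like level (median 0.0097, SD 0.0352); genes are not independent replicates, and cells are not either, so no p is given. Single names are uncertain: 43 genes were at 0.5 or above in both pools and 101 at -0.5 or below. With the order of Hopx permuted within pools the medians were 41 and 42, and 48.5% and 7.5% of 1000 permutations gave as many. The highest by the weaker of both pools included Gins4 (0.71 and 0.80), Pfdn1 (0.67 and 0.92) and Dbi (0.79 and 0.63), and the lowest Fbxo28 (-0.86 and -0.87), Cdc40 (-0.81 and -0.82) and the ribosomal protein gene Rpl11 (-0.93 and -0.70). The list fell to 94.9% in pool 1 without the cells that had both Xist and Y-linked transcripts, to 75.04% in pool 2 with Pearson correlations and to 93.4% in pool 2 with 12 clusters. The first of these settings kept 7 of the 8 cells of pool 1, and the median correlation there fell from 0.45 to 0.21. The 1 radial glia-like cell of pool 2 with Hopx at the floor (log2 level 1.61) was kept, and the list was not tested without it.

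**Figure D3:**
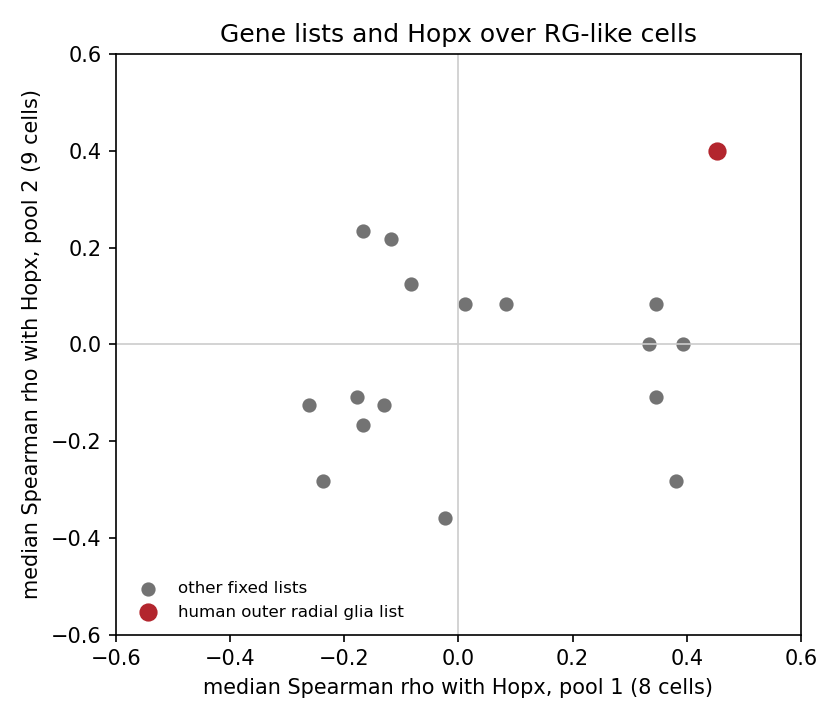
Median Spearman correlation with Hopx over radial glia-like cells for 17 fixed gene lists, in pool 1 (8 cells, horizontal axis) and pool 2 (9 cells, vertical axis); each point is 1 list. The human outer radial glia list (red) lies at 0.45 and 0.40, apart from the other lists.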

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

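Among the tests in this part, that of a uniform background of neuron RNA and both tests of the Y-linked transcripts were chosen after the result had been seen.

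Transcripts of excitatory neurons were found in radial glia-like cells, and at a like level in interneuron-like cells, which come from other progenitors (median Neurod6 91.1 and 95.2 TPM; above the floor in 16 of 17 and 24 of 27). Neurod6 ranged from 1.37 to 1514 TPM over the 17 cells, a ratio of at least 1104 since the lowest lies at its cell's floor. This ratio rests on the highest and the lowest cell alone, so it cannot decide on a uniform background of neuron RNA in every well. Over all 221 cells, most of them neurons, Neurod6 was above the floor in 217. A background of neuron RNA therefore stays open. Neurod6 went along with the mean level of 13 synapse and excitability genes (Spearman rho 0.64 over the 17 cells, 0.74 in pool 1 and 0.75 in pool 2), consistent with a neuron held in the same capture site; with the number of genes above the floor, which another cell would be thought to raise, rho was only 0.22 (3041, 2691 and 6727 genes in cells with 940.1, 772 and 1002.6 TPM of Neurod6). Cells that had begun to make neurons stay open too, since the correlation of Neurod6 with 6 intermediate progenitor markers was 0.28 over the 17 cells, between the bounds of 0.5 and 0.2 set for and against them (0.29 in pool 1; 0.15 in pool 2, below the lower bound). A cell turning into a neuron could also raise synaptic genes, but would not account for Neurod6 in interneuron-like cells, whose cause was not tested.

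Y-linked transcripts (Ddx3y, Uty, Kdm5d or Eif2s3y) were above the floor in 99 cells, although the labels give the sex as female for all 221. Xist, made from the inactive X chromosome of female cells, was above the floor in 70 cells, and 19 cells had both. Y-linked transcripts appeared in 27.1% of cells with Xist and in 53.0% of the others, an odds ratio of 0.332 with an exact upper 95% limit of 0.635, which argues against reads of X-linked homologues placed on the Y-linked genes. The odds ratio was 0.424 in pool 1 and 0.211 in pool 2, consistent with pools that held embryos of both sexes. The labels do not say whether the sex given is that of the embryos or of the mothers, and the source of the 19 cells with both was not tested.

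Of 12 sets of values (2 measures in 6 groups of 4 to 9 cells) examined for a single extreme cell, 2 had one, where chance gives about 1 in 20 groups. In pool 2, Hopx lay at the floor (log2 level 1.61), and so was not detected, in 1 radial glia-like cell, with the next at 7.51. The cell without detected Hopx had 772 TPM of Neurod6 and 2691 genes above the floor. The rate of 1 in 20 assumes normally distributed values, which values at the floor do not follow. In pool 1, 1 of the 4 intermediate progenitor-like cells had 4190 genes above the floor, against 5370 in the next. Beta-globin was above the floor in 47.1% of the excitatory neuron-like cells of pool 2 suffix B (8 of 17), against 10.8% in pool 2 suffix A. Cxcl10, an interferon-induced chemokine, was above the floor in 29.6% of the excitatory neuron-like cells of pool 1 suffix A (8 of 27), against 10.5% in pool 1 suffix B and 0 of 54 in pool 2.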

How the results depend on the processing

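Settings added after seeing the data were the FPKM scale, low-Neurod6 radial glia-like cells, the settings without suffix groups, and all comparisons with cluster 9, and for Hopx correlations the holding of Neurod6 fixed, the lists of radial glia genes and the permuted order. Scaling to equal totals and a minimum of 2000 genes change no value here and were not run. Of 3026 values of named genes under 16 alternatives, 2425 kept direction and side of the threshold, 600 kept only their direction, and 1 turned (Plxna4 RG-like vs cluster 9, 0.0279 with 12 clusters). Of 288 values of the main results, 230 were the same, 52 moved and 6 turned. For values given below the cause was not tested, except that fewer cells or other classes enter with other clusterings. Abbreviated here are radial glia-like (RG), intermediate progenitor-like (IP), excitatory neuron-like (EXC) and interneuron-like (IN).

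The log2 of the mean value gave 12 called genes for RG against IP, 426 for RG against EXC, 10 for IN against EXC and 171 for RG against cluster 9, with 8 lists for IP against EXC. Weighting by cells gave 0 for RG against IP (739 at an unadjusted p below 0.05 in limma), 48 for IP against EXC, 196 for IN against EXC, 274 for RG against cluster 9 and 35 for cluster 9 against EXC, with 7 lists for RG against IP. Pool and suffix as units gave 50 for RG against IP, 370 for RG against EXC, 44 for IP against EXC and 352 for RG against cluster 9, with 5 lists for RG against IP. No filter on low values gave 36 for IP against EXC, 28 for IN against EXC and 349 for RG against cluster 9. Quantile normalization gave 7 lists for RG against IP and 8 for IP against EXC. The FPKM scale gave 206 genes for IP against EXC. Low-Neurod6 RG cells gave 170 genes and 7 lists against IP, and leaving out cells with both Xist and Y-linked transcripts 6 lists. With 8 clusters RG against IP had 371 genes and 12 lists, and IP against EXC 0 (653 unadjusted). With 12 clusters the genes were 0 for RG against IP (1428 unadjusted), 153 for RG against EXC, 103 for RG against cluster 9, with 7 lists, and 6 for cluster 9 against EXC. Variable-gene clusters gave 0 for RG against EXC (1469 unadjusted) and 32 for IN against EXC, and shares of 19.5% RG, 0% IP, 72.9% EXC and 7.69% IN; with 8 clusters IP had 18.6%, and with 12 clusters cluster 9 had 9.05%. Variable-gene clusters gave no comparisons with IP or cluster 9.

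Hopx in RG against IP lost its call with the log2 of the mean value (2.05, adjusted p = 0.247), weighting (3.62, adjusted p = 0.337), pool and suffix units (4.55, adjusted p = 0.0874) and 12 clusters (2.42, adjusted p = 0.1804), within a range of adjusted p from 0.00228 to 0.337; against EXC it lost it with variable-gene clusters (3.05, adjusted p = 0.0976; range 3.15e-05 to 0.0976). IP against EXC passed on the FPKM scale (2.72, adjusted p = 0.0420; range 0.0420 to 0.674). The IN against EXC difference, never past the threshold, had the other sign with weighting (-0.0578), variable-gene clusters (-0.39), without cells with both Xist and Y-linked transcripts (-0.12), on the FPKM scale (-0.0550), without pool 2 suffix B (-0.36) and without pool 1 suffix A as well (-0.36). The agreement of Hopx correlations between pools was 0.243 with variable-gene clusters and 0.188 with 12 clusters; the human outer radial glia list was above 94.9% of random lists in pool 1 without cells with both transcripts, and 75.04% (Pearson) and 93.4% (12 clusters) in pool 2.

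In each pool alone, with no test, the genes called from both that kept their sign and a log2 difference of at least 1 numbered 82 for RG against IP, 763 to 770 for RG against EXC, 126 for IP against EXC, 51 for IN against EXC and 530 to 534 for RG against cluster 9; few could fail, as the calls came from these pools. Hopx was then 3.17 to 4.13, 6.33 to 6.51, 2.38 to 3.16, -0.59 to 0.62 and 4.27 to 5.91, and 0.60 to 2.06 for cluster 9 against EXC. Scaling moved the median of all genes by over 0.1 in log2 from -0.08 to 0.06 for RG against cluster 9 (FPKM scale), from 0.11 to 0.0050 for IP against EXC and from -0.07 to 0.03 for IN against EXC (both quantile). The number of cells limits all results: 17 RG and 9 IP cells in 2 pools.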

Other observations

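In this part the tests with Neurod6 held fixed and with lists drawn from radial glia genes were chosen after the pattern had been seen, though before their own values were. Mki67, a transcript of cycling cells looked up outside the rule for named genes, was above the floor in 8 of 17 radial glia-like cells (2 of 8 in pool 1, 6 of 9 in pool 2) and 4 of 9 intermediate progenitor-like cells. It was also above the floor in 8 of 32 cells of cluster 9, against 5 of 119 excitatory neuron-like and 0 of 27 interneuron-like cells. Cells with Mki67 at the floor are not counted, so these are not shares of dividing cells.

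The groups left out of the comparisons each belonged to 1 pool and suffix. Cluster 3 held 8 cells of pool 2 suffix B (median Neurod6 1338 TPM) with haemoglobin transcripts, at a mean of 2158 TPM for beta-globin and 1939 TPM for Hba-a1. Across all cells, beta-globin was above the floor in 22 of 33 cells of pool 2 suffix B, against 5 of 66 in pool 2 suffix A. Cluster 4 held 8 cells of pool 1 suffix A with a median Neurod6 of 1984 TPM, led by Ifitm3, an interferon-induced membrane protein (5 of 8 cells), and the pericyte genes Rgs5 (5 of 8) and Kcnj8 (4 of 8). Cxcl10 was above the floor in 19 of 57 cells of pool 1 suffix A, including 4 of its 7 radial glia-like cells, against 4 of 65 in pool 1 suffix B and 0 in pool 2. A single cell of pool 2 suffix B carried microglia genes (C1qb 5495 TPM, Tyrobp 5397 TPM) beside genes of oligodendrocyte precursors (Olig1 985 TPM, Pdgfra 127 TPM) and Fabp7 (23612 TPM).

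A hypothesis from these data is that the level of Hopx may rank radial glia-like cells by how far they express some genes of the human outer radial glia list. Tnc did not keep a sign (0.74 and -0.05), and Fam107a and Moxd1 were not among the members measured here. No class of apical radial glia was defined. Whether the list separates outer from other radial glia in these data was therefore not tested. Holding fixed the number of genes above the floor per cell did not bring the list below 95% of random lists in either pool. The random lists carry any effect of that number too, so this cannot decide on it as the cause. With that number held fixed, the list stayed above 99.64% of random lists in the pool where it was lower and 99.81% in the other. With Neurod6 held fixed it stayed above 99.6% and 98.4%. A varying share of neuron RNA that lowers all radial glia genes together stays open, since among lists drawn from genes called higher in radial glia-like cells it was above 95.71% in pool 2 and 98.66% in pool 1, the former too near to 95% for the spread between pools. All these random lists were drawn gene by gene, so they do not allow for genes of 1 list that vary together. The order rests on 8 and 9 cells, and the list fell to 75.04% in pool 2 with Pearson correlations.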
